A study of Rattus norvegicus with 4 samples.

How the data were processed

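RNA-seq libraries were made from ear skin of 2 Sprague Dawley rats, with 1 ear of each rat given adeno-associated virus carrying Fgf7 (AAV-Fgf7) and the other given control virus, and with tissue taken at the injection sites on day 3. Per the labels' protocols, total RNA was extracted with a column kit, and messenger RNA was enriched by poly(A) selection or ribosomal RNA was depleted, a choice the protocol leaves open. The cDNA fragments were amplified by PCR and sequenced on an Illumina NovaSeq X Plus. The titles place control virus in the left ear and AAV-Fgf7 in the right, whereas the series' design text gives the opposite sides, so ear side was not used. The descriptions of both AAV-Fgf7 samples name the same column, and the remaining treated column was assigned to rat 2 by its number and the sample title.

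The authors deposited a table of raw counts per gene and a table of FPKM (counts scaled by gene model length and by library total) for the same genes. The aligner and the read counter are not given in the sources used here. Per the submitters' processing notes, the genome build was the rat assembly Rnor_6.0 (rn6). All 54532 genes in both tables nevertheless carry mouse Ensembl identifiers and mouse chromosomes, and 0 of these identifiers occurred in a RefSeq gene table of the rat assembly GRCr8. Symbols of 5601 of the 5862 tested protein-coding genes occurred in that rat table. The sources used here do not say whether the rat reads were aligned to mouse sequence or counted on rat genes with identifiers converted later. Rows listed as mouse processed pseudogenes held 8.28% to 9.82% of the counts of a library. Conversion of rat gene identifiers would hardly yield such counts, so they argue against it. How much of each transcript a count covers is open. Alignment to mouse sequence would lose reads of genes that differ more between the species, and near-identical copies can exchange reads. The mouse build behind the listed coordinates is not given in the sources used here. Each deposited FPKM value equalled the count divided by the listed gene length and by an effective library total, which was the DESeq2 size factor times the geometric mean total (largest relative difference 5.1e-15). The group columns of the FPKM table were the authors' means of their libraries and were not used in any test.

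Library totals ranged from 1299136 to 1601321 counts, and 12902 genes had a count in at least 1 library. A low-count filter (filterByExpr of edgeR 4.0.16, in R 4.3.3) kept 6370 genes, which held 98.9% of all counts. Libraries were scaled by TMM factors (0.948 to 1.03). AAV-Fgf7 was compared with control virus by the two-sided quasi-likelihood test of edgeR, with p-values adjusted by the Benjamini-Hochberg method over the 6370 genes at a threshold of 0.05. Standard errors of log2 fold changes were taken as the fold change over the root of its F statistic. The common biological coefficient of variation was 29.1%. Levels are given as TMM-scaled counts relative to the library total (CPM) with the SD over 2 libraries, and log2 fold changes are AAV-Fgf7 over control. Counts are of reads without molecular identifiers. With 2 libraries per group, an exact permutation test of a single gene cannot give a two-sided p below 0.33, so only models that share the spread across genes were used. No pair of libraries agreed within sampling noise. A chi-square per degree of freedom over genes was 21.7 between the control libraries and 13.0 between the AAV-Fgf7 libraries, against a range of 6.92 to 23.9 between groups.

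Before the data were examined, 31 gene lists were fixed (542 members, of which 527 matched a symbol and 190 were tested). They covered FGF and MAPK feedback targets, FGF ligands and receptors, EGF family ligands, DNA replication, mitosis, keratinocyte layers, wound-activated keratinocytes, matrix remodelling, dermis, hair follicle, sebaceous gland, muscle, cartilage, fat, vessels, nerve and pigment cells, immune and blood cells, stress responses and sex-linked genes. The 23 lists with at least 3 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the lists. The rule for named genes was fixed at the same time. It took Fgf7, then up to 10 genes per direction of largest change among those past the threshold with both AAV-Fgf7 libraries beyond both controls and a mean of at least 1 CPM, and, where fewer passed, the genes of lowest p under the same conditions up to 5 per direction. It then took up to 4 members of lowest p from each list.

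The 2 ears of each rat carry the same rat number in the sample titles, so the numbers pair the libraries by animal. The deviations of same-numbered libraries from their group means correlated at r = -0.30 over the 6370 genes (Spearman -0.26), across genes that are not independent replicates, so the libraries of a rat did not deviate together. The fit with rat as a replicate block was an alternative fixed in advance. Other alternatives were RLE size factors, library totals only, DESeq2 1.42.0, limma-voom, no low-count filter, a mean count of at least 10, limma on log2(FPKM + 1) or log2(FPKM + 0.1) for genes with a mean FPKM of at least 0.5, limma on log2(FPKM + 1) with no filter, an estimated inter-gene correlation, the fry test of limma, and leaving out each library in turn. A block that crossed the rat numbers and a fit restricted to protein-coding genes other than ribosomal protein genes were added after seeing the data. The edgeR, DESeq2 and limma-voom gene tests and the camera and fry list tests were tested on simulated counts. These were drawn gene by gene without correlation, from the mean of each gene and the spread typical of genes at its level. The FPKM fits, the replicate blocks, the unfiltered gene fit and the fits without 1 library were not simulated. Among 6370 simulated genes, the edgeR test called 12% of 50 genes changed 2-fold, 78% of 50 changed 4-fold and 96% of 50 changed 8-fold. Simulated genes had no spread of their own, so these shares can overstate what the test finds in these libraries. In the data Fgf7, 9.05-fold higher in AAV-Fgf7 ears, had an adjusted p of 0.9996 in the edgeR test. In 20 simulations with the log2 values of 1 list shifted by 1, camera with the preset correlation called that list 20 times and 1 of 440 unshifted lists, whereas camera with an estimated correlation called it 0 times and fry 1 time. Because the simulated genes were uncorrelated, 1 of 440 is not the rate of false calls for lists whose genes vary together. The hair follicle list varied in this way between the controls (mean log2 of -1.58 and 1.58 around their mean). Figures were drawn with matplotlib 3.10.9. No column of per-sample values was left out.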

Results

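Transcript levels were measured by RNA-seq in ear skin of 2 Sprague Dawley rats on day 3 after injection of adeno-associated virus (AAV), a small DNA virus used to deliver genes. One ear of each rat received AAV-Fgf7, which carries the gene for fibroblast growth factor 7 (FGF7, or keratinocyte growth factor), and the other ear received control virus. Each group therefore held 2 libraries, 1 from each rat. The control libraries of rats 1 and 2 held 1299136 and 1601321 counts, and the AAV-Fgf7 libraries held 1433247 and 1417294. Of 12902 genes with a count, 6370 passed the low-count filter. The counts of these rat libraries are listed under mouse gene models, and how the reads were assigned to them is not given in the sources used here. The comparison of AAV-Fgf7 with control virus asked how skin transcripts differed when Fgf7 was delivered, in a study of epithelial repair and wound healing.

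Skin given AAV-Fgf7 held more Fgf7 transcript in both rats, although no single gene passed the edgeR test over all genes. Lists of basal keratinocyte, mitosis and DNA replication genes were higher by camera with a preset correlation, and none was called with an estimated correlation (adjusted p = 0.695 for each) or by fry. FGF7 is a secreted factor of mesenchymal cells that acts on epithelial cells through a splice form of the receptor FGFR2. Fgf7 stood at 72.3 ± 1.30 CPM in control ears and at 655 ± 473 CPM in AAV-Fgf7 ears (SD, n = 2), a log2 fold change of 3.18 (SE 0.54). Krt14 and Krt5, the keratin pair of the basal epidermal layer, had log2 fold changes of 1.54 (SE 0.39) and 1.41 (SE 0.43). Kif11, a motor protein of the mitotic spindle, had a log2 fold change of 2.01 (SE 0.53).

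Fgf7 was read in every library as a check of the labels. Its raw counts were 94 and 110 in the control ears of rats 1 and 2, and 454 and 1429 in their AAV-Fgf7 ears. The ratio of CPM between the ears was 4.49 in rat 1 and 13.5 in rat 2. The AAV-Fgf7 library of rat 2 held 3.09 times the level of that of rat 1. The authors' FPKM values for Fgf7 were 21.6 and 22.1 in control ears and 96.6 and 299 in AAV-Fgf7 ears. The gene is listed as ENSMUSG00000027208, on the plus strand of mouse chromosome 2 from 126034658 to 126091185, with a gene model of 3248 bases. Transcripts of the virus and of the animal's own gene were counted together, and a transgene without the native untranslated regions, or of another species, may have been counted in part. The animal's own transcript may also have been counted in part under the mouse gene model. The ratios between the ears may therefore be too low or too high. The edgeR quasi-likelihood test gave Fgf7 an unadjusted p of 0.00100 and an adjusted p of 0.9996 over 6370 genes. Adjusted over the list alone, that of FGF ligands and receptors, the p was 0.00703. DESeq2 called Fgf7 with an adjusted p of 9.40e-09. Without the control library of rat 1 the edgeR adjusted p of Fgf7 was 0.00117, and without that of rat 2 it was 0.000548. Without the AAV-Fgf7 library of rat 1 it was 0.185, and without that of rat 2 it was 0.9995.

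**Figure D1:**
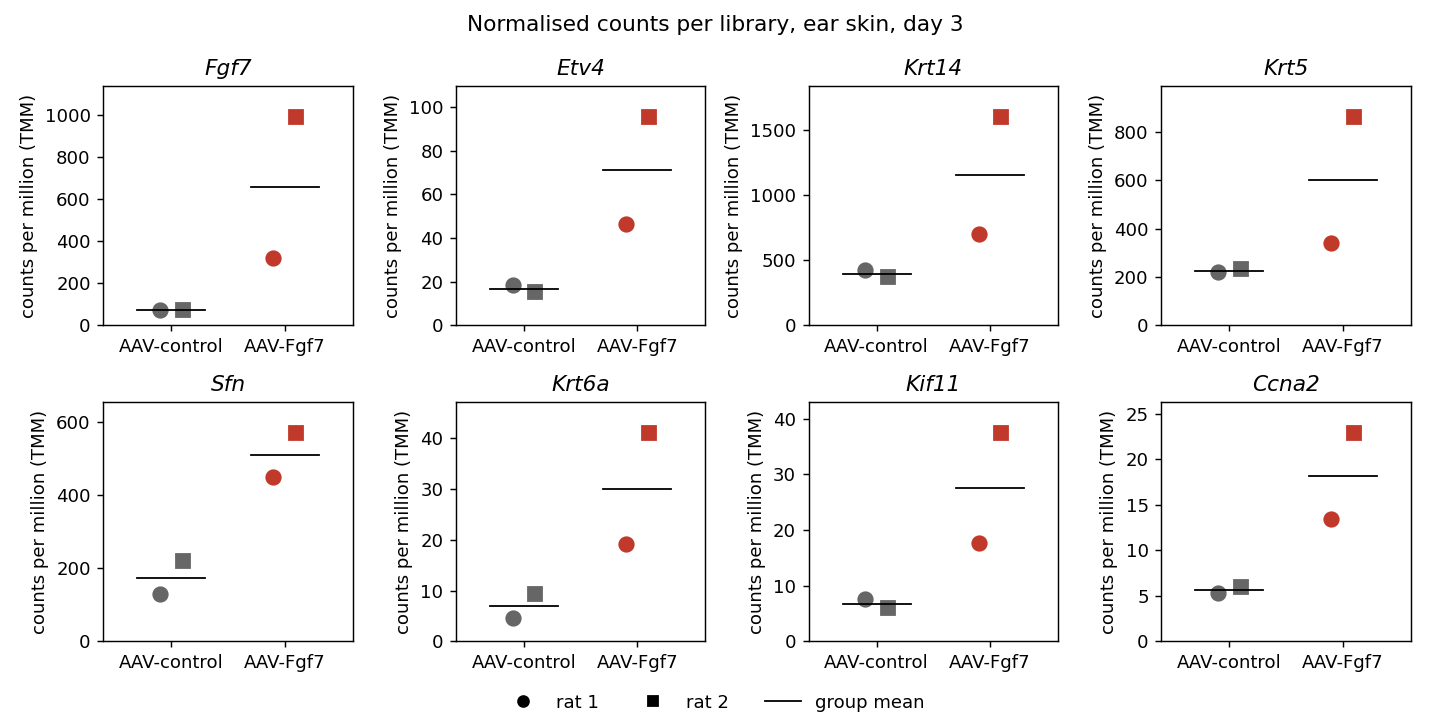
TMM-scaled normalised counts (CPM, y axis from 0) of 8 genes in each library of control and AAV-Fgf7 ears, with circles for rat 1, squares for rat 2 and a line at the group mean. For Fgf7, Etv4, Krt14, Krt5, Sfn, Krt6a, Kif11 and Ccna2 both AAV-Fgf7 libraries lay above both controls, and the AAV-Fgf7 library of rat 2 was the higher one (989 against 321 CPM for Fgf7).

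Basal keratinocyte genes were the keratinocyte list that camera called. Krt14 stood at 395 ± 35.8 CPM in control ears and 1148 ± 634 CPM in AAV-Fgf7 ears, and Krt5 at 226 ± 8.55 and 600.1 ± 370.3 CPM (SD, n = 2). Sfn, which encodes the keratinocyte adaptor protein stratifin, stood at 174 ± 64.1 and 508 ± 84.8 CPM, a log2 fold change of 1.55 (SE 0.30). Trp63, the transcription factor p63 of stratified epithelia, had a log2 fold change of 0.90 (SE 0.41). Among the 9 tested members of the list, 4 lay above both controls in both AAV-Fgf7 libraries. Hemidesmosome and basement membrane genes had log2 values of 0.75 for Itgb4, 0.31 for Itga6, -0.01 for Dst and -0.13 for Lamb3. The median log2 fold change of the list was 0.75, and camera gave an adjusted p of 0.000494 (adjusted p = 0.695 with an estimated correlation). No member passed edgeR over all genes, and 3 (Sfn, Krt14 and Krt5) passed when adjusted over the list alone by edgeR and by DESeq2. With rat as a replicate block in edgeR only Sfn did (adjusted p = 0.0238), while Krt14 and Krt5 had adjusted p = 0.0887. DESeq2 called Sfn over all genes with an adjusted p of 0.0350.

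Cell-division genes made up the other lists that camera called. Of the mitosis list, 5 of 31 members had enough counts to be tested, and 4 of them lay above both controls in both AAV-Fgf7 libraries. Kif11 stood at 6.79 ± 1.13 CPM in control ears and 27.5 ± 14.0 CPM in AAV-Fgf7 ears (SD, n = 2), from raw counts of 10 and 9 against 25 and 54. Kif20a, a kinesin of cytokinesis, had a log2 fold change of 2.35 (SE 0.68). Ccna2, which encodes the S and G2 phase cyclin A, had one of 1.66 (SE 0.51). Kif23 stood at 0.89 (SE 0.46) and Plk1 at 0.60 (SE 1.23). The median of the mitosis list was 1.66 with a camera adjusted p of 1.42e-05 (adjusted p = 0.695 with an estimated correlation). Kif11, Kif20a and Ccna2 passed edgeR when adjusted over the list alone (adjusted p = 0.0283 for each), and 0 members passed over all genes. None of them passed over the list alone by DESeq2, where the lowest adjusted p was 0.0554, or by edgeR with rat as a replicate block, where it was 0.0545. In the DNA replication list 8 members were tested, and their log2 fold changes ran from 0.18 for Rfc4 to 1.30 for Mcm5. Pcna, the sliding clamp of DNA polymerase, stood at 0.97 (SE 0.47) and the helicase subunit Mcm2 at 0.89 (SE 0.47). The list's median was 0.71, its camera adjusted p was 0.000494 (adjusted p = 0.695 with an estimated correlation), and 0 members passed over all genes or adjusted over the list alone.

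These 3 calls rested on the preset correlation between genes of a list, and fry gave an adjusted p of 0.717 for each. The mitosis list was called in each of the 4 fits that left out 1 library, but such fits hold a lone library in 1 group. They also called the skeletal muscle list lower without the control of rat 1 and higher without that of rat 2. A call in such a fit is therefore no support for a list. Without the AAV-Fgf7 library of rat 2 the adjusted p was 0.0513 for basal keratinocyte and 0.0620 for DNA replication, and without the control library of rat 2 it was 0.0505 for DNA replication. Markers of other tissues in the ear also differed between these libraries. Summed CPM of the skeletal muscle list was 15328 and 64410 in the control libraries of rats 1 and 2 and 33521 and 16275 in their AAV-Fgf7 libraries. The hair follicle list summed to 247 and 1468 CPM in the controls and 4264 and 348 CPM in the AAV-Fgf7 libraries.

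**Figure D2:**
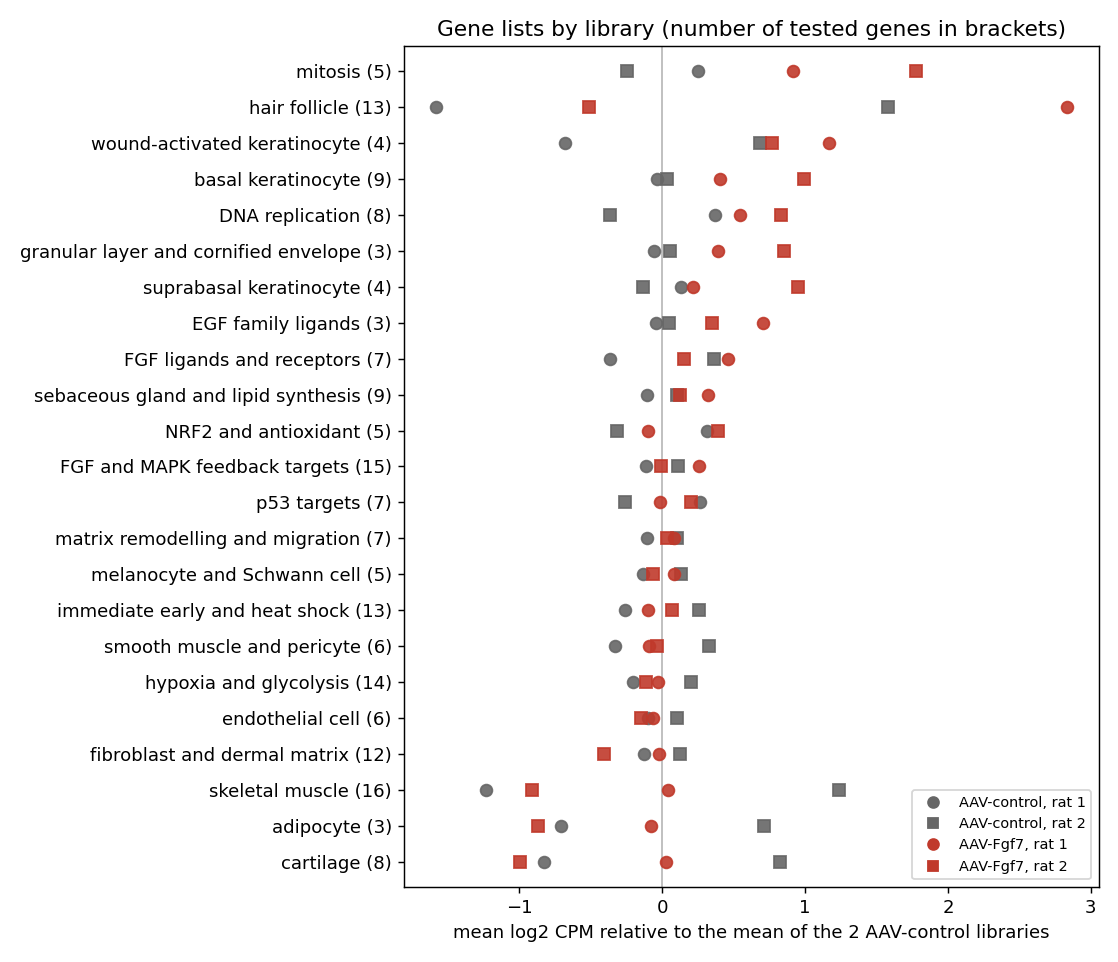
Mean log2 CPM of the tested genes of 23 lists in each library, relative to the mean of the 2 control libraries (x axis), with grey for control, red for AAV-Fgf7, circles for rat 1 and squares for rat 2. Both AAV-Fgf7 libraries lay above both controls for mitosis (0.91 and 1.78) and basal keratinocyte (0.41 and 0.99). The same held for the DNA replication, suprabasal, granular layer, wound-activated, EGF family and sebaceous gland lists. The hair follicle list ranged from -1.58 to 1.58 between the controls alone.

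Differentiated and wound-activated keratinocyte genes had positive medians but were not called. Krt10, the main keratin of the spinous layer, had a log2 fold change of 1.20 (SE 0.52), with raw counts of 1197 and 875 in control ears and 1206 and 3710 in AAV-Fgf7 ears. Serpinb5, which encodes the epithelial serpin maspin, stood at 1.20 (SE 0.45), and Krt2, a keratin of the upper spinous layer, at -0.07 (SE 0.56). The suprabasal list (4 tested) had a median of 0.63 and an adjusted p of 0.0982. Adjusted over the list alone, 0 of its members passed edgeR, whereas Krt10 (adjusted p = 0.0201) and Serpinb5 (adjusted p = 0.0417) passed DESeq2. In the granular layer list (3 tested), Asprv1, a protease that processes filaggrin, stood at 1.54 (SE 0.56), the lipid transporter gene Abca12 at 0.75 (SE 0.49), and the list's adjusted p was 0.0794. Krt6a, a keratin induced at wound edges, stood at 6.94 ± 3.37 CPM in control ears and 30.0 ± 15.4 CPM in AAV-Fgf7 ears (SD, n = 2), a log2 fold change of 2.08 (SE 0.58). It passed when adjusted over the list alone by edgeR (adjusted p = 0.0450), DESeq2 (0.0322) and edgeR with the block (0.0316), while Krt17 stood at 0.77 (SE 0.48). The wound-activated list (4 tested) had a median of 0.76 and an adjusted p of 0.0654, which became 0.0235 with rat as a replicate block. Without the block its adjusted p was 0.765 with an estimated correlation and 0.970 by fry. The 3 tested members of the EGF family list were all receptor genes, with Erbb2 at 0.91 (SE 0.54), Egfr at 0.36 (SE 0.63) and Erbb3 at 0.35 (SE 0.69). That list had an adjusted p of 0.0794, which became 0.0470 with the block, and without the block the adjusted p was 0.695 with an estimated correlation and 0.717 by fry.

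Among transcripts downstream of FGF receptors, Etv4 stood apart. Etv4 encodes an ETS transcription factor induced by FGF signalling through ERK, and it stood at 16.8 ± 2.06 CPM in control ears and 71.1 ± 34.6 CPM in AAV-Fgf7 ears (SD, n = 2). Its log2 fold change was 2.08 (SE 0.44), with an adjusted p of 0.0452 over the list alone by edgeR, 0.00326 by DESeq2 and 0.163 by edgeR with rat as a replicate block. Of the phosphatase and Sprouty feedback genes, Dusp4 stood at 0.95 (SE 0.45), Dusp6 at 0.12 (SE 0.29), Dusp5 at -0.83 (SE 0.58) and Spry4 at -0.90 (SE 0.68). The list of FGF and MAPK feedback targets (15 tested) had a median of 0.11 and an adjusted p of 0.518. Of the receptors, Fgfr2 stood at -0.20 (SE 0.19) and Fgfr1 at -0.43 (SE 0.39). The list of FGF ligands and receptors (7 tested) had an adjusted p of 0.948, with a median of -0.20, a mean of 0.32 and an upward direction in camera, so that these differed in sign.

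Over all genes, edgeR called 0 of 6370 at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 148 genes, 109 higher and 39 lower in AAV-Fgf7 ears, fewer than the 318.5 that chance would give. DESeq2 called 3 genes, all higher (Fgf7, H2afv and Sfn), with 84 at an unadjusted p under 0.05, and limma-voom called 0 with 131. Both AAV-Fgf7 libraries lay beyond both controls for 1790 genes, or 28.1% against the 33.3% that chance gives. When either control library was left out, edgeR called genes that included Fgf7 and H2afv. They also included muscle genes such as Myh7 and Ckm without the control of rat 1, and hair keratins such as Krt71 and Krt25 without that of rat 2. Such calls rest on a lone control library, and genes of these tissues varied widely between the controls. No gene was called without either of the AAV-Fgf7 libraries.

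The genes of lowest p outside the lists included some with few counts in one group. H2afv, a histone variant gene, had raw counts of 7 and 4 in control ears and 131 and 69 in AAV-Fgf7 ears, a log2 fold change of 4.13 (SE 0.55) and a DESeq2 adjusted p of 2.80e-05. Rps2, a ribosomal protein gene, had counts of 1 and 2 against 23 and 28, and Kpna2, an importin gene, 1 and 0 against 16 and 17. In the other direction, Rabac1, which encodes a Rab acceptor protein, had counts of 56 and 48 in control ears and 7 and 3 in AAV-Fgf7 ears (log2 fold change -3.38, SE 0.52). Tes3-ps stood at -2.02, the phosphatase gene Acp1 at -1.56, the cytoskeletal adaptor gene Obsl1 at -1.58 and the tetraspanin gene Cd63 at -0.78. Comparable switches between libraries also occurred without regard to the virus. Counts of Rpl10a were 4 and 6 in the libraries of rat 1 and 913 and 1250 in those of rat 2.

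Genes of muscle, cartilage and hair follicle varied widely within each group. All 16 tested skeletal muscle genes had negative log2 fold changes (median -0.74, camera adjusted p = 0.0794), and 0 of them lay below both controls in both AAV-Fgf7 libraries. Myh7, a slow-fibre myosin gene, had raw counts of 2 and 423 in control ears and 56 and 28 in AAV-Fgf7 ears. All 8 tested cartilage genes were negative (median -0.53, adjusted p = 0.0971). Col2a1, the main collagen of cartilage, had counts of 45 and 633 against 222 and 31. The hair follicle list (13 tested) had a median of 1.46 and an adjusted p of 0.0794. Krt25, an inner root sheath keratin, had counts of 7 and 164 against 882 and 10. The adipocyte list (3 tested) had a median of -0.61 and an adjusted p of 0.261. Its lipid droplet gene Plin1 stood at -0.89 (SE 0.64).

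Dermal, vascular and stress lists were not called either. The fibroblast and dermal matrix list (12 tested) had a median of -0.19 and an adjusted p of 0.0971, with the collagen gene Col1a2 at -0.68 (SE 0.26). Adjusted p-values were 0.582 for endothelial cells (6 tested), 0.886 for smooth muscle and pericytes (6 tested), and 0.961 for matrix remodelling (7 tested) and for melanocytes and Schwann cells (5 tested). The sebaceous gland list (9 tested) had an adjusted p of 0.261, with Awat1, a wax ester synthase gene, at 1.16 (SE 0.38). In the hypoxia and glycolysis list (14 tested, adjusted p = 0.518), Bnip3, a mitophagy gene, stood at -1.07 (SE 0.33) and the hexokinase gene Hk1 at 1.42 (SE 0.57). Adjusted p-values were 0.606 for immediate early and heat shock genes (13 tested), 0.851 for NRF2 and antioxidant genes (5 tested) and 0.961 for p53 targets (7 tested). Median and mean differed in sign for immediate early genes (0.12 and -0.11), p53 targets (-0.14 and 0.05) and matrix remodelling (-0.09 and 0.07). Immediate early genes included Fosb, whose counts were 20 and 468 in control ears and 20 and 36 in AAV-Fgf7 ears.

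Immune and blood cell lists had too few tested members for a list test. The macrophage list summed to 382 and 148 CPM in control ears and 205 and 278 CPM in AAV-Fgf7 ears. Of its 2 tested members, the receptor gene Csf1r stood at a log2 fold change of -0.10 (SE 0.38) and Aif1 at -0.20 (SE 0.75). T and NK cell genes summed to 46.3 and 2.66 against 17.7 and 37.4 CPM. Only 2 of 17 members had a count, and most of the sum was Lck (41.0 CPM in the control ear of rat 1). Neutrophil and acute inflammation genes summed to 23.5 and 0 against 3.53 and 12.5 CPM. Only 2 of 22 members had a count, and Nos2 alone stood at 23.5 and 0 against 2.82 and 11.1 CPM. These sums therefore do not measure the amount of a cell type. Interferon response genes, of which 9 of 28 had a count, summed to 19.0 and 0.666 against 14.1 and 20.8 CPM. Of these, Rsad2 stood at 15.2 and 0 against 6.36 and 12.5 CPM. Mast cell genes summed to 41.0 and 37.3 against 44.5 and 33.9 CPM, and red blood cell genes to 130 and 114 against 121 and 74.1 CPM. B and plasma cell genes had no counts in any library. The sex-linked list, which holds Xist and Y-linked genes, had 0 tested members. Only 1 of its 5 genes had a count (0.706 CPM in the AAV-Fgf7 library of rat 1 and 0 in the others). Reads may have been lost under the mouse gene models, so a lack of counts does not show that a transcript or cell type was absent.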

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

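The crossed replicate block and the fit restricted to protein-coding genes other than ribosomal protein genes were chosen after seeing the data, and the other alternatives before. The edgeR count of 0 changed genes held with RLE factors, library totals only, limma-voom, a mean count of at least 10, the 3 FPKM fits (pseudocount 1 with and without the filter, 0.1 with it), the restricted gene set and the edgeR replicate block (75 genes at an unadjusted p under 0.05). DESeq2 called 3 genes, all higher and all changed 2-fold or more, with Fgf7 at a log2 fold change of 3.18 past the threshold. With no low-count filter edgeR called 3 (2 higher, 1 lower, all 2-fold or more), with Fgf7 at 3.18 and past the threshold. DESeq2 with the replicate block called 2, both higher and 2-fold or more, with Fgf7 at 2.96. Leaving out each library in turn gave 0 to 59 genes changed, 0 to 32 higher, 0 to 42 lower, 0 to 59 changed 2-fold or more and an Fgf7 log2 fold change of 2.15 to 3.77, with the lone library assumed to vary like the others. The 3 called lists became 0 with an estimated correlation, 0 with fry, 5 with the replicate block, 6 with no low-count filter, 3 with RLE factors and 4 to 9 without each library. The replicate block added the wound-activated keratinocyte list and the EGF family list, whose tested members were receptors, and changed no other list call. With the rat numbers crossed, edgeR called 0 genes and camera 7 lists, 5 higher and 2 lower. Beyond the 3 of the main fit these were the wound-activated keratinocyte, skeletal muscle, cartilage and hair follicle lists. Without the control library of rat 2, Myh7 reversed to a log2 fold change of 4.20 and the skeletal muscle list was called higher (adjusted p 0.000783). Over the 4 fits without 1 library, Myh7 ranged from -3.25 to 4.20 and the list's adjusted p from 5.955e-12 (lower, without the control of rat 1) to 0.963. The cause of these changes was not tested. Of 1747 alternative values of 103 named genes other than Fgf7, 1635 kept their direction and side of the threshold, 87 changed sign with no call in either fit, 24 gained a call and 1 reversed. With 0 calls to begin with, none had a call to lose. Only 190 of 542 fixed list members had enough counts to be tested.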

Other observations

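Apart from Dsc1, a suprabasal list member with too few counts to be tested, the genes of this paragraph lie outside the fixed lists. They were chosen after their values were seen, so their counts test nothing. Of 18 genes of desmosomes, the junctions that tie keratinocytes together, 7 had enough counts to be tested and 5 lay above both controls in both AAV-Fgf7 libraries, as did 942 of all 6370 tested genes (14.8%). The plakophilin genes Pkp1 and Pkp3 stood at 0.99 (SE 0.26) and 1.25 (SE 0.37), desmoplakin (Dsp) at 0.72 (SE 0.22) and plakoglobin (Jup) at 0.90 (SE 0.32), whereas Pkp4 stood at -0.16 (SE 0.21). The epidermal transcription factor gene Tfap2a stood at 0.95 (SE 0.23), and its raw counts were 83 and 90 in control ears and 160 and 179 in AAV-Fgf7 ears. Trim29, a gene of stratified epithelia, stood at 0.89 (SE 0.22). Among single genes of low p, Wnt4 stood at 1.32 (SE 0.35), Wnt10a at 1.26 (SE 0.38) and Bmp7 at 1.61 (SE 0.35). None of these genes passed the edgeR test over all genes (adjusted p = 0.9996 for each).

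Of the tests reported here, that of gene copies and that of tissue amounts behind the deviations by rat number were fixed before their results were seen. The other 4, which include the tests of this paragraph, were chosen after. The basal keratinocyte, mitosis and DNA replication lists were called higher in AAV-Fgf7 ears with the preset correlation. Less muscle or cartilage in the AAV-Fgf7 pieces would raise the markers of every other cell type alike. The mean log2 was 0.74 ± 0.65 (SD) over 9 basal keratinocyte members and -0.18 ± 0.25 over 18 fibroblast and endothelial members. An exact permutation of members gave a two-sided p = 2.52e-05, across genes that are not independent replicates. The basal list was taken because camera had called it higher in the same libraries, so this p restates that call and cannot exclude the cause. The fibroblast and endothelial members, not picked by a call, were not raised on average. Summed muscle and cartilage CPM was lower in the control of rat 1 (15328 and 675) than in the AAV-Fgf7 libraries of rat 1 (33521 and 1199) and rat 2 (16275 and 687). Relative to the control mean, its basal keratinocyte log2 was -0.04, against 0.41 and 0.99. The control of rat 2, with 64410 CPM of muscle, stood at 0.04. For the basal list these values argue against less muscle or cartilage as the cause. A larger share of epidermis, or less dermis, in the pieces stays open. The 16 basal, suprabasal and granular members had a common log2 change of 0.54 (SE 0.12). This SE and the Q below treat the genes as independent, although all were measured in the same 4 libraries. They do not measure the spread between rats. Cochran's Q over these genes (n = 16) was 23.3, p = 0.0778 by its chi-square distribution. It used standard errors taken from each p on the normal scale, which are larger than the SE printed for these genes. Q with the printed SE would be larger and was not computed, so whether these genes share 1 common change is not settled. The cell-cycle part was not tested. A response of keratinocytes to the delivered Fgf7 also stays open as untested, because a thicker or more proliferative epidermis would give the same values.

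Some genes, most of them with common cellular functions, were close to 0 in one group only (H2afv, Rps2, Kpna2, Psma2 and Ehf in control ears, Rabac1 in AAV-Fgf7 ears). Leaving out Fgf7 and genes of the tissue lists, 6 genes switched by virus, 9 by rat number and 25 across the remaining split of the 4 libraries (19 when all keratin and keratin-associated genes are left out too, with muscle genes such as Myh6 still among them), so switching unrelated to the virus may account for them. Reads shared between near-identical copies are a further candidate explanation. An annotated pseudogene was present for 4 of the 11 protein-coding genes that switched by virus or rat number and passed the low-count filter (36.4%) and for 139 of 5851 other tested ones (2.38%, odds ratio 23.4, Fisher's exact two-sided p = 9.81e-05). Among the 4 were 2 of the 6 genes that switched by virus, which were not tested alone. An effect of Fgf7 on these genes stays open as untested.

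The libraries of one rat deviated from their group means in opposite directions (r = -0.30 over 6370 genes), and the first principal component (51.3% of variance) set the control of rat 2 and the AAV-Fgf7 library of rat 1 apart from the other libraries. Replicate numbers exchanged within one group cannot be told apart from true pairing. Among ribosomal protein genes only 3 switched by number and 1 across (exact binomial p = 0.625). So few genes cannot give a p under 0.05 in this test whatever their split, so it decides nothing. With 3 pseudogenes of unnamed parent genes added, the counts were 6 and 1 (exact binomial p = 0.125). Different amounts of hair follicle, muscle and cartilage in the pieces are consistent with the correlation of 0.389 over 111 housekeeping genes, against -0.62 over 37 genes of those tissues. Without genes that switch, the housekeeping value was 0.04 over 105 genes, so it rested on the switching genes. Biological differences between the rats were not tested.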
